A study of Curvibacter sp. AEP1.3 with 15 samples.

How the data were processed

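Curvibacter sp. AEP1.3 was grown in 500 ml of R2A broth at 18 °C to an optical density of 0.145, and the signal or the solvent was then present for 4 h, per the labels' protocols. RNA was extracted with a Qiagen RNeasy kit and libraries were made with a stranded Illumina TruSeq kit with Ribo-Zero depletion of ribosomal RNA, per the labels. The deposited values are counts per gene, made by the authors with featureCounts of Subread 1.4.6-p3 in paired-end mode from a gene table, per the file headers, and bcl2fastq 2.16.0.10 is named in the submitters' processing notes. The aligner and the genome build are not given in the sources used here, and positions are those of the deposited files. The command in the file header sets no strand option, so reads of both strands were counted together and reads from a gene and an overlapping gene on the other strand cannot be told apart. Of the 4115 genes, 754 overlap the next gene by 1 bp or more, a count that does not set apart neighbours on the other strand. The 6 features in a duplicated block at 2088733 to 2099746 come in pairs of equal length, and their counts are uncertain if the copies share reads. Multi-mapping reads were not asked for in that command.

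The counts of 15 libraries in 3 groups of 5 were analysed as deposited. The table of the whole series holds the same counts and was not used. Total counts ranged from 6270839 to 15553704. Intervals are of differences between groups, rest on the spread between libraries and take the libraries as independent. Genes were kept by edgeR's filterByExpr, which removed 16. TMM factors averaged 1.05 in solvent, 0.919 with 3OC12-HSL and 1.04 with 3OHC12-HSL. CPM values are scaled by these factors. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust estimates, all groups in the same fit and no block, and Benjamini-Hochberg adjustment within each comparison at 0.05. Fold changes and their 95% intervals come from that fit. No covariate was set, since the labels name none.

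The rule for named genes was fixed before the data were examined. Where no gene names can be had, it gives the 2 largest rises and the 2 largest falls per comparison, among genes with an adjusted p of 0.05 or less and a mean log2 CPM of at least 2. The 27 gene lists fixed then could not be matched to any gene, because the files do not pair identifiers with names, and no reference annotation was used here. Runs are at least 3 consecutive genes on the same strand of a contig, each called and changed at least 2-fold in the same direction. Values of a run are sums of CPM over its genes.

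The share of counts on the 49 features of 74 to 93 bp divided the libraries at 0.35%. This division was found in the data and is not a label. It was used as a term in the fit and, where a set held both groups, to limit the libraries compared. Because it is defined from the short features themselves, it is not an independent measure for them.

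The fit was tested on simulated data with known changes in 200 genes for each comparison. For 3OC12-HSL against solvent it recovered 76% of the 1.25-fold and 98% of the 2-fold changes among 4096 genes and called 7 of 3896 unchanged genes. For 3OHC12-HSL against solvent it recovered 78% and 100% among 4097 genes and called 8 of 3897. For 3OC12-HSL against 3OHC12-HSL it recovered 58% and 98% among 4098 genes and called 11 of 3898. The simulated counts were drawn independently from the spread that the fit itself had estimated, with no library sets. They thus do not measure how many calls in the real data are false. Alternatives tried were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma voom with quality weights, only the groups compared, the replicate number as a block, adjusted p thresholds of 0.01 and 0.1, each library left out in turn, and the settings on short features. Shared controls were treated by simulation of 3 unchanged groups, solvent included, and by divisions of the solvent libraries. No pair of libraries within a group agreed within sampling noise, with the lowest chi-square per degree of freedom at 3.67. Figures were drawn with matplotlib 3.10.9.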

Results

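RNA was sequenced from liquid cultures of Curvibacter sp. AEP1.3, a bacterium that lives on the freshwater polyp Hydra. The cultures had received an acyl-homoserine lactone, a class of signal molecule with which many bacteria sense their own density, or the solvent alone. Both signals carry the same acyl chain and differ at the third carbon, where 3OC12-HSL has a keto group and 3OHC12-HSL a hydroxyl group. Each was added at 10 µM for 4 h, and the solvent cultures received ethyl acetate with acetic acid at a dilution of 1 in 2000. Each of the 3 conditions had 5 libraries, which the design text calls biological replicates. The files hold counts for 4115 genes on 2 contigs, and 4099 genes had enough counts to be tested. Total counts per library lay between 6270839 and 15553704, with a median of 7994264. The files do not pair gene identifiers with names or products, so genes are given by identifier and position and no pathway was tested.

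The first comparison asked how the bacterium responds to the unmodified signal, 3OC12-HSL. The gene AEP_01802, on contig 1 at 1943483 to 1943665 (183 bp, plus strand), rose from 104 ± 7.5 CPM (library-scaled counts; SD, n = 5) in solvent to 19806 ± 831 CPM (SD, n = 5), a 190-fold change. AEP_00879, on contig 1 at 933706 to 934872, rose 10.9-fold, from 157 ± 10.5 to 1710 ± 38.5 CPM (SD, n = 5). The adjacent genes AEP_02356 (2517514 to 2517852) and AEP_02355 (2515986 to 2517494) fell: AEP_02356 fell by 3.18 and AEP_02355 fell by 2.89 on the log2 scale. AEP_02356 went from 224 ± 23.0 to 24.7 ± 2.2 CPM and AEP_02355 from 578 ± 51.3 to 78.2 ± 10.5 CPM (SD, n = 5). In edgeR's quasi-likelihood test the adjusted p was 1.33e-22 for AEP_01802, 5.99e-21 for AEP_00879, 1.73e-11 for AEP_02356 and 7.97e-13 for AEP_02355.

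Neighbouring genes changed together with 3OC12-HSL. There were 12 runs of at least 3 consecutive genes on the same strand that were each called and changed at least 2-fold in the same direction, holding 48 genes, with 8 runs higher and 4 lower. The rule for runs was set after gene names proved to be absent from the files. The run of 6 genes at 1420469 to 1427927 rose from a summed 399 ± 10.6 to 1821 ± 30.1 CPM (SD, n = 5). The 4 genes at 788693 to 792497 fell from 454 ± 21.2 to 116 ± 8.9 CPM, and the 6 genes at 2046745 to 2054429 fell from 2486 ± 95.9 to 828 ± 72.9 CPM (SD, n = 5). The abundant run of 6 genes at 2421996 to 2426885 fell from 11062 ± 135 to 5118 ± 445 CPM (SD, n = 5). The 3 genes at 4266070 to 4271985 fell from 602 ± 37.9 to 227 ± 12.3 CPM (SD, n = 5). Smaller rises included 4 genes at 1513723 to 1517449, from 152 ± 7.5 to 377 ± 14.1 CPM, and 3 genes at 2587415 to 2590829, from 110 ± 4.9 to 269 ± 17.8 CPM (SD, n = 5).

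Across the genome, 2027 of 4099 genes were called at an adjusted p of 0.05, 1096 higher and 931 lower with 3OC12-HSL. With only the groups compared in the fit, 945 were higher and 1094 lower, so neither direction prevailed in both fits. Most changes were small, with a median absolute log2 fold change of 0.33 among called genes, and 91 genes changed at least 2-fold, 61 higher and 30 lower. The libraries fell into sets by the share of counts on features shorter than 100 bp, which split the 3OC12-HSL group. Within the 8 libraries of higher share, all 5 solvent libraries and 3 of 3OC12-HSL, 2055 genes were called. Of the 2027 genes, 1742 were among them in the same direction.

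**Figure D1:**
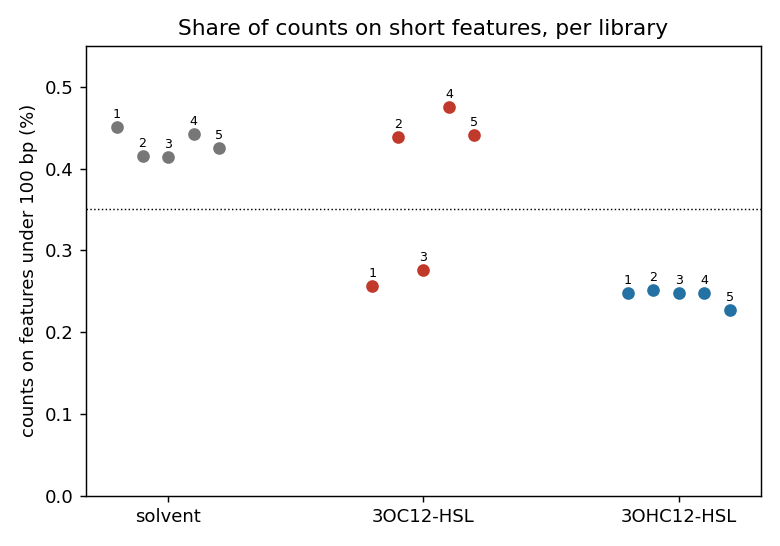
Percent of counts on features shorter than 100 bp in each of the 15 libraries, by group. Points are libraries with their replicate number and the dotted line marks 0.35%. The solvent libraries lie between 0.414% and 0.451%, the 3OHC12-HSL libraries between 0.227% and 0.252%, and 3OC12-HSL replicates 1 and 3 lie below the line at 0.257% and 0.276%.

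The second comparison asked how the bacterium responds to the reduced signal, 3OHC12-HSL. AEP_01802 again showed the largest rise, to 12819 ± 1429 CPM (SD, n = 5), or 123-fold over solvent (edgeR adjusted p = 3.73e-22). AEP_01268, on contig 1 at 1337230 to 1337667, rose 22.1-fold from 2.85 ± 0.52 to 63.0 ± 14.9 CPM (SD, n = 5; edgeR adjusted p = 1.35e-11). The 9 consecutive genes at 43904 to 51708 rose from a summed 351 ± 150 to 2969 ± 390 CPM (SD, n = 5), and all 9 were called, with a median log2 change of 2.88 (3.49 with the short-feature set of the library as a term). The run of 6 genes at 1420469 to 1427927 rose to 2054 ± 71.0 CPM, and 3 genes at 1133361 to 1135908 rose from 20.4 ± 1.7 to 58.6 ± 13.8 CPM (SD, n = 5).

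The largest falls with 3OHC12-HSL were in short features. AEP_00308 (347028 to 347103, 76 bp) went from 68.4 ± 9.2 to 21.4 ± 2.5 CPM and AEP_00877 (930350 to 930436, 87 bp) from 150 ± 5.7 to 51.0 ± 4.5 CPM (SD, n = 5). Their edgeR adjusted p was 3.12e-08 and 9.42e-15. Of the 48 tested features under 100 bp, 35 were lower and 1 was higher, with a median log2 change of -0.65. All 5 3OHC12-HSL libraries belong to the set of lower short-feature share and all 5 solvent libraries to the other, so no set holds both groups. With that set as a term in the fit, which rests on the split 3OC12-HSL group, the log2 change was -1.26 for AEP_00308 and -1.49 for AEP_00877, and the median over the 48 features was -0.05. A run of 3 short features at 1447400 to 1447762 had a median log2 change of -1.27 without the term and 0.19 with it.

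In total 1664 genes were called with 3OHC12-HSL, 828 higher and 836 lower, and 90 changed at least 2-fold, 73 higher and 17 lower. Of those 17 genes, 12 were short features. With the short-feature set as a term 1451 genes were called, and 974 of the 1664 genes were called in the same direction. Of the 90 genes with at least a 2-fold change, 82 were called in the same direction with the term. The term rests on the split 3OC12-HSL group and takes the set difference to be the same with both signals. These counts thus do not settle how far the comparison with solvent depends on the set.

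The third comparison set the signals against each other at the same dose and time. The level of AEP_00879 with the keto and the hydroxyl form differed by less than the spread between replicates, at 1710 ± 38.5 and 1680 ± 80.4 CPM (SD, n = 5), with a log2 difference of 0.03 (95% interval -0.08 to 0.13; edgeR adjusted p = 0.674). AEP_01802 was 1.54-fold higher with the keto form (log2 difference 0.63, 95% interval 0.48 to 0.77; edgeR adjusted p = 1.98e-07). Higher with the keto form were AEP_03904 (4155653 to 4156630), at 433 ± 16.8 against 102 ± 11.4 CPM, and AEP_02415 (2586020 to 2587216), at 393 ± 29.1 against 106 ± 6.8 CPM (SD, n = 5). Higher with the hydroxyl form were AEP_01268, at 63.0 ± 14.9 against 4.86 ± 0.92 CPM, and AEP_01538 (1608991 to 1609326), at 77.1 ± 22.6 against 6.23 ± 1.7 CPM (SD, n = 5). The edgeR adjusted p was 1.55e-15 for AEP_03904, 2.34e-16 for AEP_02415, 1.00e-11 for AEP_01268 and 7.57e-09 for AEP_01538.

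Some regions moved in opposite directions with the signals. The 4 genes at 788693 to 792497 fell to 116 ± 8.9 CPM with 3OC12-HSL and were at 552 ± 13.8 CPM with 3OHC12-HSL, above the solvent level of 454 ± 21.2 CPM (SD, n = 5). All 4 genes were called lower with the former, higher with the latter and different between the signals. The 6 genes at 2046745 to 2054429 did likewise, at 828 ± 72.9 CPM with 3OC12-HSL and 3435 ± 173 CPM with 3OHC12-HSL (SD, n = 5). The reverse order held for 4 genes at 2228743 to 2231049, with 23916 ± 1712 CPM in 3OC12-HSL, 15078 ± 449 CPM in solvent and 10628 ± 633 CPM in 3OHC12-HSL, and for 5 genes at 3134223 to 3136191, with 20756 ± 1914, 13065 ± 348 and 8509 ± 1050 CPM (SD, n = 5). For these 4 runs, in the order given, the median log2 change with 3OHC12-HSL against solvent was 0.26, 0.40, -0.50 and -0.61. No short-feature set holds both of those groups. The 3OHC12-HSL side of these orders thus cannot be told apart from a difference between the library sets. The 9 genes at 43904 to 51708 did not move in opposite directions. With 3OC12-HSL they were at 557 ± 264 CPM against 351 ± 150 CPM in solvent (SD, n = 5). The median log2 change was 0.73 and 1 of 9 was called higher. At each replicate number the 3OC12-HSL library lay above the solvent library, from 374 against 202 CPM in replicate 1 to 1018 against 581 CPM in replicate 5. The fit, which has no block, does not use this. All 9 genes were called lower with 3OC12-HSL than with 3OHC12-HSL.

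**Figure D2:**
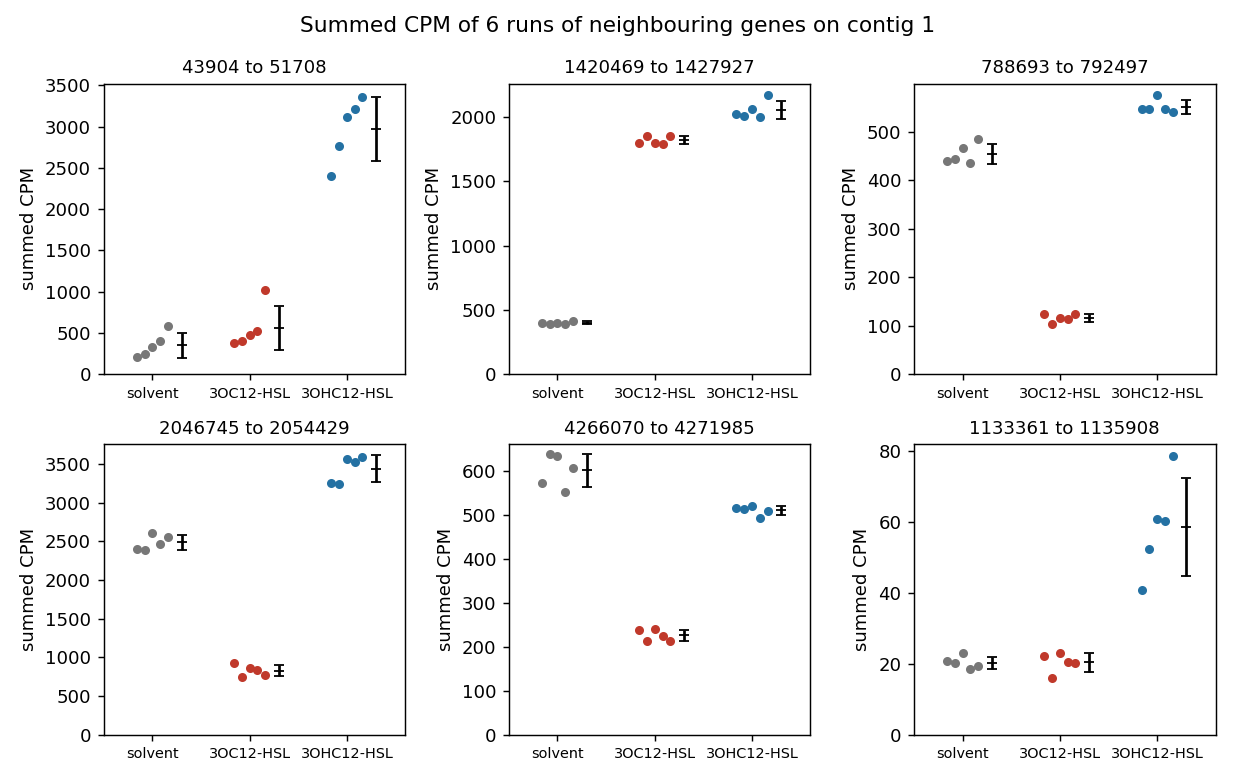
Summed CPM of the 6 runs of neighbouring genes on contig 1 with the largest median log2 changes, runs of short features and overlapping runs left out, titled by start and end. Points are the 5 libraries of each group, bars are the mean with its SD, and the vertical axes start at 0. With 3OC12-HSL the 4 genes at 788693 to 792497 average 116 CPM against 454 in solvent and 552 with 3OHC12-HSL.

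The direct test called 2433 of 4099 genes, 1196 higher and 1237 lower with 3OC12-HSL, and 165 differed at least 2-fold, 81 higher and 84 lower. Within the 7 libraries of lower short-feature share, 2 of 3OC12-HSL and 5 of 3OHC12-HSL, 2327 genes were called. Of the 2433 genes, 1994 were among them in the same direction. Of the 81 genes, 13 were short features.

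The overlap of the responses was tested with the solvent libraries in mind, since both comparisons share them. A total of 528 genes were called in the same direction with both signals, and 409 were called in opposite directions, where independent lists of these sizes would give 412. The pooled 409 joins 2 unlike parts. Higher with 3OC12-HSL and lower with 3OHC12-HSL were 263 genes, where independent lists would give 224. Lower with 3OC12-HSL and higher with 3OHC12-HSL were 146, where they would give 188. Of the 528, the direct test called 271 different in level, and for 248 of the other 257 the 95% interval of the log2 difference lay within 0.5 of 0. At least 2-fold higher with both signals were 15 genes. Both signals raised 290 genes, where independent lists of these sizes would share 221, and lowered 238, where they would share 190. With separate solvent libraries for each signal, which leaves fewer controls, the shared counts averaged 184 (166 to 221) and 143 (127 to 165), where independent lists would share 135 and 114. Simulated unchanged groups had at most 2 called genes in a comparison, so their shared count of 0 raised genes gives no scale for this overlap. The log2 changes correlated across genes, which are not independent replicates, with Pearson's r of 0.32 and Spearman's rho of 0.17. The covariance was 0.053, against 0.006 in 100 simulations of unchanged groups with shared controls, in which r averaged 0.50 and rho 0.47. With separate solvent libraries, r averaged 0.29 over 20 divisions, between 0.17 and 0.38, rho averaged 0.11, between -0.01 and 0.20, and the covariance averaged 0.049. Without the 3 genes raised over 8-fold by both signals r was 0.24. The set of lower short-feature share holds 5 3OHC12-HSL, 2 3OC12-HSL and 0 solvent libraries. A set difference could thus move both comparisons the same way, and separate solvent libraries do not remove it. Its part in the counts shared by the signals was not tested.

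**Figure D3:**
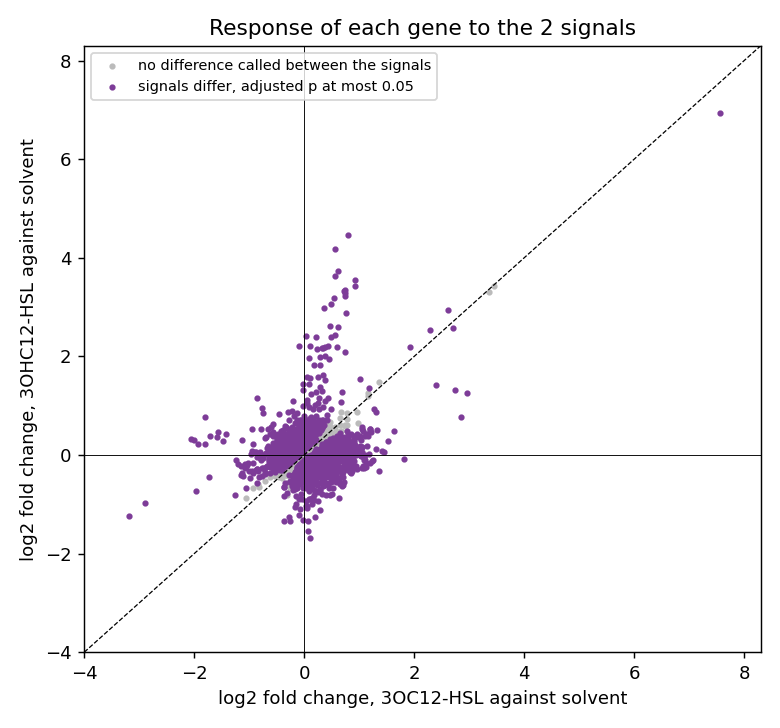
Log2 fold change of each of 4099 genes with 3OHC12-HSL (vertical axis) against that with 3OC12-HSL (horizontal axis), each relative to solvent. The dashed line marks equal change and purple points are the 2433 genes called different between the signals. The point at the upper right is AEP_01802, at 7.57 and 6.94.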

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

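The tests of this part on the region at 43904 to 51708 and on the short features were chosen after the result was seen. Of 111 groups of 5 values examined, 7 held a library far from the other 4, where chance gives about 1 in 20, or 5.55. The sum over 43904 to 51708 was 1018 CPM in 3OC12-HSL replicate 5, against 374 to 524 CPM in the others. In 3OHC12-HSL replicate 5, the sum over 2421996 to 2426885 was 8226 CPM against 9575 to 10037, the short-feature share was 0.227% against 0.247% to 0.252%, contig 2 took 0.347% of counts against 0.410% to 0.427%, and the most abundant gene took 7.45% against 6.19% to 6.37%. These measures come from the same library and are not independent. AEP_00879 was at 138 CPM in solvent replicate 4, against 160 to 164 CPM. The sum over 788693 to 792497 was 576 CPM in 3OHC12-HSL replicate 3, against 542 to 547 CPM.

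The rise of the 9 genes at 43904 to 51708 with 3OHC12-HSL does not rest on a single library, since the lowest median log2 change with a library left out was 2.78. With the short-feature share as a term the median was 3.49. That term rests on the split 3OC12-HSL group, as no share set holds both solvent and 3OHC12-HSL libraries, so it cannot exclude a set difference. The 2 3OC12-HSL libraries of lower share lay at 374 and 468 CPM, so lower share did not go with a comparable rise there. The 5 3OHC12-HSL libraries lay at 2397 to 3363 CPM and the 5 solvent libraries at 202 to 581 CPM. A response to 3OHC12-HSL is a hypothesis, tested on the data it was found in, and a difference between the library sets is not excluded.

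The share of counts on short features was lower in each 3OHC12-HSL library than in each solvent library. Against solvent, the median log2 change of the 48 features was -0.65, and -0.054 with the short-feature set of the library as a term, so the term took up nearly all of the median fall. This does not settle the matter, because the set is defined from the same features. A trend with length is not decided, since features from 100 to under 200 bp had a median of 0.055 with quartiles of -0.24 and 0.27. Within the libraries of lower share, the features had a median log2 of 0.36 for 3OC12-HSL over 3OHC12-HSL, against an SD of 0.12 between the medians of the 3OHC12-HSL libraries, with 23 of 48 called higher and 3 lower. The signals thus differed within a set, which does not say which of them departed from solvent. Against solvent, a response to 3OHC12-HSL cannot be told apart from a difference between the library sets, because 0 of the share sets hold both solvent and 3OHC12-HSL libraries.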

How the results depend on the processing

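The settings on short features were added after seeing the data. The 3 counts of called genes and the 3 counts at 2-fold stayed within 1.5 times their value under each alternative run. The share of higher genes among those called lay between 46.3% and 55.7% for 3OC12-HSL against solvent, 46.6% and 54.1% for 3OHC12-HSL against solvent and 46.3% and 50.3% between the signals, on both sides of 50% in each. With a library left out, called genes ranged from 1864 to 2037 for 3OC12-HSL against solvent, from 1515 to 1582 for 3OHC12-HSL against solvent and from 2296 to 2408 between the signals. The correlation of the signals ranged from 0.29 to 0.35. With the short-feature set as a term the run at 1447400 to 1447762 changed sign, to a median of 0.19, as its 3 members are short features that define the set. That term also ended 690 of the 1664 calls with 3OHC12-HSL or turned their direction, 3 of them turned; the cause was not tested. Of the named-gene values under settings that left out no library, 248 counted as unchanged, 2 fell short of the threshold and 4 passed it. With a library left out, 300 of 300 counted as unchanged. For a value called in the main fit, unchanged means still called in the same direction. A value not called there also counted as unchanged where its sign changed, so for such values the counts do not show a kept direction. Of the values for runs of genes, 263 moved by less than the spread between libraries and 10 by more, in the same direction and with a short-feature setting each time, and with a library left out 310 moved by less. The replicate numbers do not pair the cultures by the rule fixed beforehand, since 9 of 15 same-numbered pairs correlated over 0.1 and the lowest was -0.12. As a hint from the data, same-numbered pairs averaged 0.156 and others -0.038 (1-sided exact permutation p = 0.0144 for the mean of same-numbered pairs), although only 4 of 15 libraries correlated best with their own number in both other groups. With the replicate block 2180, 1776 and 2511 genes were called. The alternatives for the gene lists and for removing rRNA and tRNA rows were not run, as the files name no gene. Real group labels called 2027, 1664 and 2433 genes. Of 100 splits of the 10 libraries each, 1 gave as many, the real split. The highest other split called 1, 1 and 758 genes. Of the 126 possible splits in each comparison 100 were run. Mixed splits carry the group difference in their spread, so low counts were likely there and the splits do not exclude chance. They also cannot tell the signal from a difference between the library sets. The 758 came from exchanging 3OC12-HSL replicate 5 with 3OHC12-HSL replicate 1.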

Other observations

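The permutation test of covariation within groups was set before its result was seen, and the other tests of this part were chosen after. Contig 2, of 20 genes, had 10 genes higher and 0 lower with 3OC12-HSL by edgeR, with a median log2 change of 0.37, and 4 higher and 0 lower with 3OHC12-HSL. Among 4060 windows of 20 neighbouring genes on contig 1, 4.83% had a median as high. The windows overlap. The contig took 0.475% and 0.450% of counts in the 2 3OC12-HSL libraries of lower short-feature share, and 0.372%, 0.433% and 0.347% in replicates 2, 4 and 5, against 0.304% to 0.393% in solvent. Within the libraries of higher short-feature share the median was 0.24, with 7 genes higher and 0 lower. A shift of the whole contig with 3OC12-HSL is thus a borderline hypothesis, and the library set goes with part of its size. Genes changed at least 2-fold lay beside each other more than chance placement gives, with 48, 21 and 62 genes in runs for the 3 comparisons in the order of the report, against at most 3, 3 and 6 over 1000 shuffles of positions.

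Within groups, the 9 genes at 43904 to 51708 were compared with 64 other genes raised by 3OHC12-HSL. Over 15 libraries the deviations from the group means gave Pearson's r of 0.86 (2-sided permutation p = 1e-05, the smallest that 100000 resamples can give) and Spearman's rho of 0.90 (permutation p = 1e-05). Without the 2 farthest libraries r was 0.75. These p-values treat the libraries as independent within groups, which is in doubt. In all 3 groups this region's level rose in the order of the replicate numbers (Kendall's W of 1, 1-sided exact permutation p = 6.94e-05). With whole replicate numbers permuted the exact p of r was 0.00833, the smallest that 120 permutations can give. Of 1000 random sets of 64 other genes, 0.6% had an r as far from 0. The 64 genes thus shared the spread of the region between replicate numbers. With the means of the numbers removed, which takes out what same-numbered cultures share, r was -0.37 and rho -0.24, so no positive relation was seen beyond the numbers. Same-numbered cultures may have shared a condition that goes with the level of this region, although the labels name none and the genome-wide rule did not pair them. This region was singled out from many, which the p does not count.

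The gene at 1943723 to 1944475 lies on the other strand from AEP_01802, with 57 bp between the ends of the 2 genes, and was looked at after its values were seen. It went from 45.0 ± 1.9 CPM in solvent to 238 ± 26.0 with 3OC12-HSL and 120 ± 6.1 with 3OHC12-HSL (SD, n = 5). Counting without strand could have added reads of AEP_01802 to it. Its added CPM was 0.984% ± 0.149 of that of AEP_01802 with 3OC12-HSL and 0.599% ± 0.079 with 3OHC12-HSL (SD, n = 5; exact permutation p = 0.00794, 2-sided), which argues against a fixed share of those reads as the only source. A share that differs between the signals stays open.

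The abundant gene at 4214481 to 4214856 was at 14470 CPM on average in the 2 3OC12-HSL libraries of lower short-feature share and at 58245 CPM in the other 3. Solvent averaged 48268 CPM and 3OHC12-HSL 62750 CPM. The 5 3OHC12-HSL libraries, all of lower short-feature share, lay at 59395 to 69522 CPM. The low level of the 2 3OC12-HSL libraries was thus not seen in the 3OHC12-HSL libraries of the same set. The short-feature term takes the set difference to be the same with both signals. For this gene that cannot be tested, because the set of higher share holds 0 3OHC12-HSL libraries.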
